A study of Mus musculus with 12 samples.

How the data were processed

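Lungs were dissected from mouse embryos at embryonic day 12.5 on a C57BL/6 background, bred from parents that carried an Intu knockout allele, and left and right lungs were kept apart, per the labels. Total RNA was extracted with a column kit and libraries were made by a sequencing company, per the labels' protocols. There were 12 libraries, 3 numbered ones for each genotype and side.

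The deposited values are raw counts of reads per gene, not normalised. Reads were checked with FastQC, aligned with HISAT2 to GRCm38 and counted with featureCounts, per the submitters' processing notes; the versions and whether counting used strand are not given in the sources used here. The table gives the Ensembl ID, exon coordinates and counts of each gene. As used here it ends within a row on chromosome 8, and that 1 incomplete row was left out, which leaves 31078 genes on chromosomes 1 to 7, 10, X and part of 8. The rest of the genome, the Y chromosome included, was not analysed here. The total of 10290103 to 10753386 counts per library is therefore only part of each library's depth. Gene symbols were matched by ID for 30915 of the genes (99.5%). Of the 543 genes in the lists fixed beforehand, 290 were in the table and 255 were tested.

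Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), which kept 9519, and libraries were scaled with TMM factors between 0.992 and 1.01. Groups were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) in 1 fit of all 12 libraries with 4 groups, 8 residual degrees of freedom and no covariate, and p-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. The comparisons were knockout against wild type in left lungs, in right lungs and as their mean, left against right in each genotype, and the interaction. Fold changes are given on the log2 scale with the test's standard error (SE), and normalised CPM as mean ± SD of 3 libraries. The 20 most abundant genes took 6.45% to 6.94% of the counts. Replicates of one group differed beyond sampling noise (chi-square per degree of freedom between 4.58 and 13.6), so none was a duplicate. Nothing in the labels says that the libraries of a group came from separate embryos, so p-values measure only the spread between these samples, which may be technical.

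Gene lists were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with an estimated one, adjusted over 31 lists per comparison. Of the 33 lists fixed before the data were examined, the sex-linked list was used only to check samples and the stomach and oesophagus list had 1 tested gene. Genes were named by a rule also fixed beforehand: Intu, Gli1 and Hhip in every comparison (Ptch1 was not analysed here), 1 more gene between sides, the 8 largest changes in each direction among called genes with at least 1 CPM and non-overlapping groups, and up to 4 called members of each list, or the 2 with the smallest p where none was called. Genes called only in the paired fits, other list members (among them Ccnd1, Ccnd2, Des, Laptm5, Mrc1, Sox5, Sox6 and Elavl4), Hoxaas2 and the genes of the closing section were chosen after their values were seen. Some genes that the rule names are not reported here.

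The numbers in the labels were checked for pairing before calls were compared. Deviations from the group means of the left and right library with one number correlated at 0.253 to 0.486 in all 6 pairs within a genotype, against -0.393 to -0.00284 for different numbers, and at -0.121 to -0.0416 for left and right libraries of one number across genotypes. The numbers were therefore taken to pair left and right within a genotype, a hint from the data and not a statement of the labels. Fits with each pair as a block are given beside the results they change; the list tests with pairs were added after seeing the data.

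The procedure was tested on simulated counts of 9519 genes with 200 changed, at first with no pairs. For the mean comparison, 73.1% of genes changed 1.5-fold, 91% of those changed 2-fold and 92.4% of those changed 4-fold were called, with 4 unchanged genes called. For the left comparison the shares were 61.2%, 77.6% and 92.4% (8 unchanged genes called) and for the right comparison 56.7%, 61.2% and 95.5% (9). For left against right they were 61.2%, 77.6% and 92.4% in wild type (4) and 55.2%, 79.1% and 93.9% in the knockout (14). The Benjamini-Hochberg threshold is stricter where fewer genes change. In the data 1 and 0 genes were called between sides without pairs, so these shares may be too high for those comparisons. With simulated pairs, the paired fit called 56.7%, 82.1% and 92.4% in wild type (11) and 59.7%, 68.7% and 89.4% in the knockout (8). For the mean comparison with simulated pairs, correlated as in the data (0.341), a test added after the data were examined, the fit of 12 libraries called 68.7%, 79.1% and 98.5% (25 unchanged genes called), and the fit of left and right counts summed 64.2%, 70.1% and 98.5% (8). In a simulation, without pairs, of 32 lists for the mean comparison, camera called 4 of 4 shifted lists and 0 of the others. Its lists were random genes simulated without correlation, and every member of the 4 largest lists was changed 1.5-fold. It therefore does not test small lists or lists of correlated genes, such as glycolysis with an estimated correlation of 0.772. Alternatives covered scaling, filters, DESeq2 1.42.0, limma-voom, replicate blocks, fits of the groups compared alone, and leaving out the X chromosome or each library in turn.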

Results

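Gene expression was measured by RNA sequencing in lungs of mouse embryos at embryonic day 12.5, the stage at which the airways branch and the first airway smooth muscle forms. The study compared embryos with a knockout of Intu, a gene of the CPLANE complex that is needed to build primary cilia, with wild-type embryos, and compared left with right lung. There were 4 groups (wild-type left, wild-type right, Intu-knockout left and Intu-knockout right) of 3 libraries each. The part of the count table used here covers chromosomes 1 to 7, 10 and X and part of chromosome 8, and holds between 10290103 and 10753386 counts per library. Of its 31078 genes, 9519 had enough counts to be tested. Genes elsewhere in the genome, among them Ptch1, Foxf1 and Acta2, were not analysed here. Normalised levels are given as counts-per-million (CPM) relative to this part of each library.

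Intu itself, on chromosome 3 (40531286 to 40704774, GRCm38), was checked first. Its level was 31.2 ± 1.13 CPM in wild-type left and 31.8 ± 3.10 in wild-type right lungs, against 26.9 ± 0.67 in knockout-labelled left and 29.5 ± 1.69 in knockout-labelled right lungs (SD, n = 3 each). The log2 difference over both sides was -0.16 (SE 0.06), with an adjusted p of 0.162 in edgeR's quasi-likelihood test, so the summed count of Intu did not separate the labels. The labels do not say which part of the gene the allele removes, and a count over all exons does not test for a small deletion or a frameshift. The genotypes are therefore given below as the libraries were labelled. Gli1 (chromosome 10, 127329882 to 127341974), a transcription factor and direct target of Hedgehog signalling, did separate them: its lowest wild-type library held 344.6 CPM and its highest knockout-labelled library 185.5.

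The first comparison asked what changes in the lung when Intu is lost. Over both sides, 3 of 5 measured members of the fixed list of Hedgehog targets were lower in knockout-labelled lungs, among them Gli1 and Hhip. Gli1 fell by 1.10 on the log2 scale (SE 0.05, adjusted p = 1.54e-08), from 367 ± 25.1 to 176 ± 9.07 CPM in left lungs and from 359 ± 16.7 to 164 ± 15.1 in right lungs. Hhip, which encodes a Hedgehog-binding protein, fell by 0.85 (SE 0.08, adjusted p = 3.81e-05). The cell cycle genes Ccnd1 and Ccnd2, also on the list, stood at -0.01 each (adjusted p = 0.891 and 0.927). The list as a whole was called lower by limma's camera test (adjusted p = 0.000115), but not with an estimated correlation between genes (adjusted p = 0.0666 with an estimated correlation).

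The smooth muscle list showed the broadest change. All 6 of its measured members were lower in knockout-labelled lungs, and it was the 1 list called with both the preset correlation (adjusted p = 2.66e-14) and the estimated one (adjusted p = 0.00229 with an estimated correlation). Actg2, the enteric smooth muscle actin, fell by 1.99 on the log2 scale (SE 0.07, adjusted p = 6.92e-10), from 219 ± 25.2 to 55.8 ± 3.65 CPM on the left. Synpo2, an actin-bundling protein encoded on chromosome 3, fell by 2.04 (SE 0.08), Lmod1 by 0.92 and the myosin light chain Myl9 by 0.91. Hhip is also on this list. Des, the intermediate filament desmin, moved least, at -0.29 (adjusted p = 0.0166), and was the 1 member that was not called when the left and right counts of one number were summed. Actc1, an actin of heart and early muscle, fell by 1.70 (SE 0.18, adjusted p = 7.03e-05), while Myl2, a ventricular myosin light chain on the same cardiac list, was higher by 2.60 at group means under 4 CPM and was not called after summing (adjusted p = 0.124). The cardiac list was not called as a set (adjusted p = 0.45).

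Genes of autonomic neurons and their precursors were lower as well. Of 13 measured members of the list for neurons and neural crest, 7 fell and none rose. Phox2a, a transcription factor of autonomic neurons, fell by 2.13 (SE 0.27), Hand2 by 1.75 (SE 0.27) and Stmn2, a neuronal tubulin-binding protein on chromosome 3, by 1.43 (SE 0.15). Ret and Elavl4 fell by 0.66 and 0.58. The list was called lower with the preset correlation (adjusted p = 0.00241), but not otherwise (adjusted p = 0.394 with an estimated correlation). Adjusted over the list alone, 7 were lower and 2 higher. With left and right counts summed, Ret and Elavl4 were not called (adjusted p = 0.11 and 0.112).

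Macrophage genes moved in the same direction. Of 10 measured members of the myeloid list, all had negative values and 6 were called, among them Spi1, the transcription factor of the myeloid lineage (-0.75, SE 0.14, adjusted p = 0.0055), Tyrobp (-0.61, SE 0.12), C1qb (-0.58, SE 0.09) and Fcer1g (-0.57, SE 0.11). The list was called with the preset correlation (adjusted p = 6.54e-09) and not with the estimated one (adjusted p = 0.118 with an estimated correlation). Adjusted over the list alone, 7 members were lower. After summing left and right, 2 of the 6 were called, Laptm5 (-0.53) and Mrc1 (-0.43).

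Other genes rose. The cartilage matrix genes Matn4, Col9a2 and Col9a3 were higher by 1.16 (SE 0.08, adjusted p = 1.15e-06), 0.48 (SE 0.07) and 0.42 (SE 0.11), whereas the chondrocyte regulators Sox5 and Sox6 stood at -0.03 and 0.06; 3 of 8 measured members were called and the list was not (adjusted p = 0.0637; 0.0201 and 0.0173 without the knockout-labelled pairs number 2 and 3). The matrix genes Acan, Col9a1 and Col11a1 on the cartilage list stood at -0.76, -0.03 and 0.06 with left and right counts summed. None of these was called in that edgeR fit (adjusted p = 0.413, 0.957 and 0.652). Among mesenchymal transcription factors, Prrx1 rose by 0.86 (SE 0.09, adjusted p = 7.03e-05) and Tbx3 by 0.21 (SE 0.04). Wif1, a secreted Wnt inhibitor, rose by 1.64 (SE 0.23, adjusted p = 0.000598), while Wnt2b and the Wnt feedback gene Nkd1 fell by 0.68 and 0.25. In the BMP and TGF-beta list, Bmp7 fell by 0.41 (SE 0.05, adjusted p = 0.00036) and Tgfb1 by 0.27, and Id1 and the BMP antagonist Grem1 were higher by 0.25 and 0.77. Matn4, Col9a2, Prrx1, Wif1, Bmp7 and Tgfb1 were also called with left and right counts summed, and Col9a3, Tbx3, Wnt2b, Nkd1, Id1 and Grem1 were not (adjusted p = 0.215, 0.0913, 0.14, 0.0991, 0.185 and 0.269).

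Genes of glycolysis and the response to low oxygen were higher: 6 of 12 measured members were called, and all 12 had positive values. Pdk1, which limits pyruvate oxidation, was higher by 0.78 (SE 0.20), P4ha1 by 0.68 (SE 0.18), Ldha by 0.54 (SE 0.12) and Aldoa by 0.50 (SE 0.13). In the knockout-labelled pair number 2, Pdk1 reached 192.9 CPM on the left and 191.8 on the right, against 82.25 to 109.6 in the other 4 knockout-labelled libraries. Without that pair the median of the list went from 0.46 to 0.24, with 6 members called. Without the wild-type pairs number 1, 2 and 3, 0, 0 and 1 members were called, and with left and right counts summed none was. The list was called whichever of the 6 pairs was left out (adjusted p at most 0.000707). The list's call (adjusted p = 3.87e-05) was lost with an estimated correlation (adjusted p = 0.507 with an estimated correlation).

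The genes with the largest changes were expressed at low levels. The 8 largest decreases among genes whose groups did not overlap included those of Tnmd (-3.12, SE 0.22), which encodes tenomodulin of tendon cells, the neuropeptide gene Calcb (-2.53, SE 0.23), the transcription factor Sall1 (-2.28, SE 0.31), Tnn (-2.24), Phox2a and the neuroendocrine transcription factor Insm1 (-2.07, SE 0.31). The 8 largest increases included those of Pax7, a transcription factor of muscle progenitors (3.42, SE 0.54), Caln1 (2.22, SE 0.34), Igfbpl1 (2.22, SE 0.25) and Slpi (1.78, SE 0.28), all at means under 15 CPM. The unnamed genes Gm12666, Gm37070 and Gm5900 were also among them. Rpl21-ps10, which rose, and Rpl21-ps11 and Gm5148, which fell, are on chromosome 3; the first 2 are pseudogene copies of a ribosomal protein gene, and reads may be split between such copies by the counting, so these values are uncertain.

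**Figure D1:**
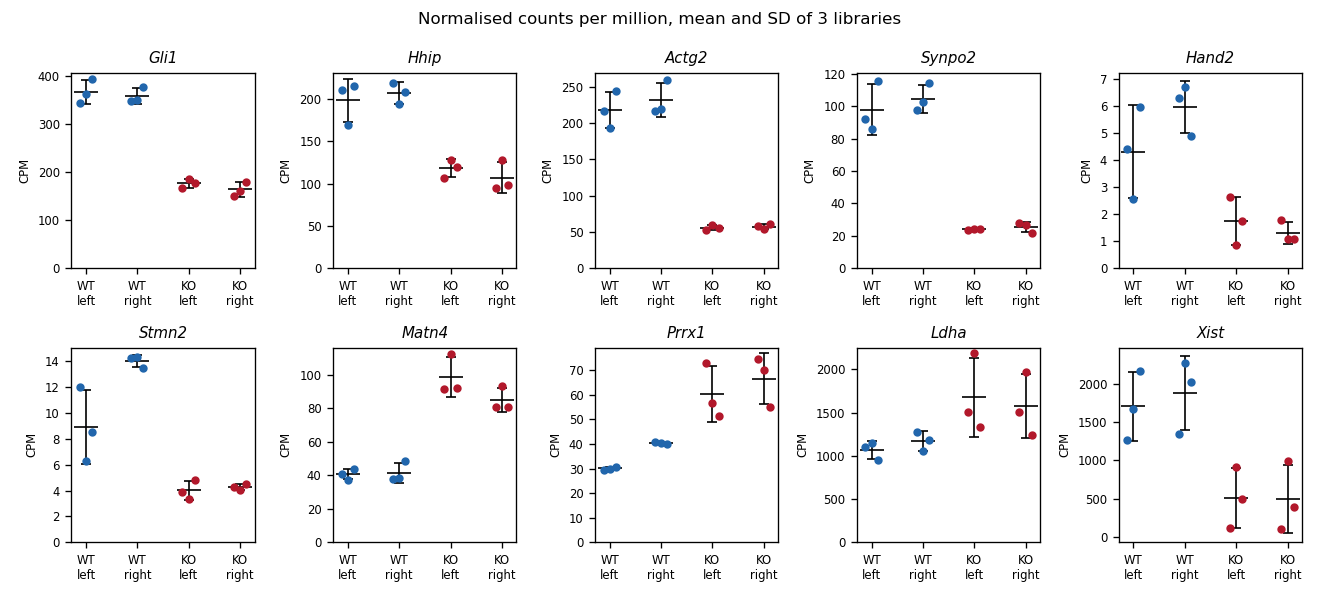
Normalised CPM of 10 genes in each library (points), with the mean (bar) and SD of 3 libraries, for wild-type (WT, blue) and knockout-labelled (KO, red) left and right lungs. Gli1, Hhip, Actg2 and Synpo2 are lower in every knockout-labelled library than in any wild-type library, Matn4 and Prrx1 are higher, and Xist ranges from 107.2 to 985.4 CPM within the knockout-labelled right group.

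In all, 543 of 9519 genes were called over both sides at a 5% false discovery rate, 198 higher and 345 lower in knockout-labelled lungs. This fit treats 12 libraries as independent, although same-numbered left and right libraries deviated together; on simulated counts with such pairs and 200 changed genes it also called 25 unchanged ones, more than the 5% rate allows, and the summed fit 8. With the left and right counts of each number summed, which leaves 3 against 3, 141 genes were called (35 higher, 106 lower), of which 138 were shared with the 543. With the pairs as a random effect in limma-voom, 344 genes were called (108 higher, 236 lower). Without the wild-type pair number 2, 263 genes were called, and without the knockout-labelled pair number 3, 331; without the wild-type right library number 2 alone, 354.

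The other lists gave no call as a set over both sides, with adjusted p-values from 0.0637 (cartilage) and 0.125 (immediate-early genes; 0.0139 without the knockout-labelled pair number 2) to 0.996 (retinoic acid). None of 3 measured CPLANE genes, 5 retinoic acid genes, 4 left-right asymmetry genes, 10 erythroid genes, 10 p53 targets, 3 hepatic genes and 1 stomach and oesophagus gene was called. A single gene was called in each of several lists: Scube2 (0.81) among 13 Hedgehog pathway components, Fat4 (0.31) among 8 planar cell polarity genes, Bbs7 (-0.39) among 22 primary cilium genes, Dnaic1 (-1.31) among 3 motile cilium genes, Elf3 (0.54) among 9 lung epithelial genes, Ret among 2 distal tip genes, Spry1 (-0.30) among 7 FGF genes, Sox18 (0.21) among 9 endothelial genes, Upk3b (-0.32) among 6 mesothelial genes, Pax7 among 4 skeletal muscle genes, Cenpf (0.20) among 17 proliferation genes and Ier2 (-0.25) among 5 immediate-early genes. Of 4 proximal airway genes 1 was lower, of 16 matrix genes Col3a1 rose (0.19) and Tnc fell (-0.78), and of 8 Hox genes Hoxd8 rose (1.20) and Hoxa7 fell (-0.75). Fat4, Bbs7 and Spry1 lie on chromosome 3 within 10 Mb of Intu, a region with an excess of called genes that is taken up below. Apart from Pax7, none of the genes named in these sentences was called with left and right counts summed. Adjusted over the list alone, the largest differences from these counts were in the glycolysis list, with 9 of 12 higher, and the Wnt list, with 2 higher and 5 lower of 13.

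Libraries also differed in a marker of sex. Xist, which is transcribed from the inactive X chromosome in female cells, stood at 1702 and 1876 CPM in wild-type left and right lungs and at 508.5 and 493.5 in knockout-labelled ones. The log2 difference was -1.83 (SE 0.47, adjusted p = 0.0357; adjusted p = 0.216 with left and right summed). Alb, a liver gene, was at 40.29 CPM in the knockout-labelled left library number 1 and under 3 CPM in each of the other 11 libraries. In a principal component analysis of log2 CPM, the first component (28.7% of the variance) separated the genotypes, and the next ones (14.6% and 11.9%) separated numbers within a genotype.

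The comparison was then made on each side alone. In left lungs 112 genes were called (29 higher, 83 lower in knockout-labelled libraries) and in right lungs 144 (32 higher, 112 lower). On the left, Gli1, Hhip, Actg2, Synpo2, Myl9, Lmod1, Actc1, Stmn2, Bmp7, Mrc1 and Laptm5 fell and Matn4, Prrx1, Wif1, Pax7, Igfbpl1 and the renin gene Ren1 (1.90, SE 0.33) rose. On the right 3 of 5 measured Hedgehog targets were called lower, with Gli1 at -1.13 (SE 0.07) and Hhip at -0.95 (SE 0.12). Actg2, Synpo2, Lmod1, Actc1, Phox2a, Hand2, Stmn2, C1qb and Laptm5 also fell, and Matn4, Col9a2, Prrx1, Wif1 and Alx1 (1.56, SE 0.31) rose. As sets, camera called 4 lists on the left (Hedgehog targets, smooth muscle and myeloid lower, glycolysis higher) and 6 on the right (those 4, neurons lower and cartilage higher). Smooth muscle alone held on each side (adjusted p = 0.00158 on the left and 0.00155 on the right with an estimated correlation). The other calls were lost, with adjusted p = 0.051, 0.154 and 0.596 with an estimated correlation for Hedgehog targets, myeloid genes and glycolysis on the left, and 0.0599, 0.141, 0.718, 0.253 and 0.253 for these, neurons and cartilage on the right. No single glycolysis gene was called on either side by edgeR; adjusted over the list alone, 9 were higher on the left and 0 on the right. The counts depended on single libraries: without the wild-type left library number 1 the left count was 45, and without the wild-type right library number 2 or the knockout-labelled right library number 3 the right count was 68. With only the groups compared in the fit, 49 genes were called on the left.

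Of the genes called, 17 were higher and 61 lower on both sides, against 0.0975 and 0.977 for independent lists of these sizes. Of the 178 genes called on either side, 176 had the same sign on both, and their log2 fold changes correlated with a Pearson r of 0.909 (0.669 over all tested genes; r is across genes, which are not independent replicates). Part of this excess may come from the pairing of same-numbered left and right libraries. A genotype by side interaction tested whether the effect of the knockout differed between sides. Without pairs no gene was called in edgeR, with 124 genes at an unadjusted p under 0.05 against 476 expected by chance, and DESeq2 and limma-voom also called 0. That edgeR fit ignores the pairs of left and right libraries, so the low number is not evidence against an interaction. Without the filter on low counts some genes were called, as given below. With the pairs as blocks, 2 genes were called by edgeR, Gm10705 and Adarb1 (407 genes at an unadjusted p under 0.05), and 0 by limma-voom with the pairs as a random effect (335 genes at an unadjusted p under 0.05). Camera called the neuronal list without pairs, a call lost with an estimated correlation (adjusted p = 0.7 with an estimated correlation). With pairs it called 5 lists: neuronal, Hox (adjusted p = 0.00427 each), retinoic acid (0.0086), glycolysis (0.0159) and erythroid genes (0.0199), and none with pairs and an estimated correlation.

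**Figure D2:**
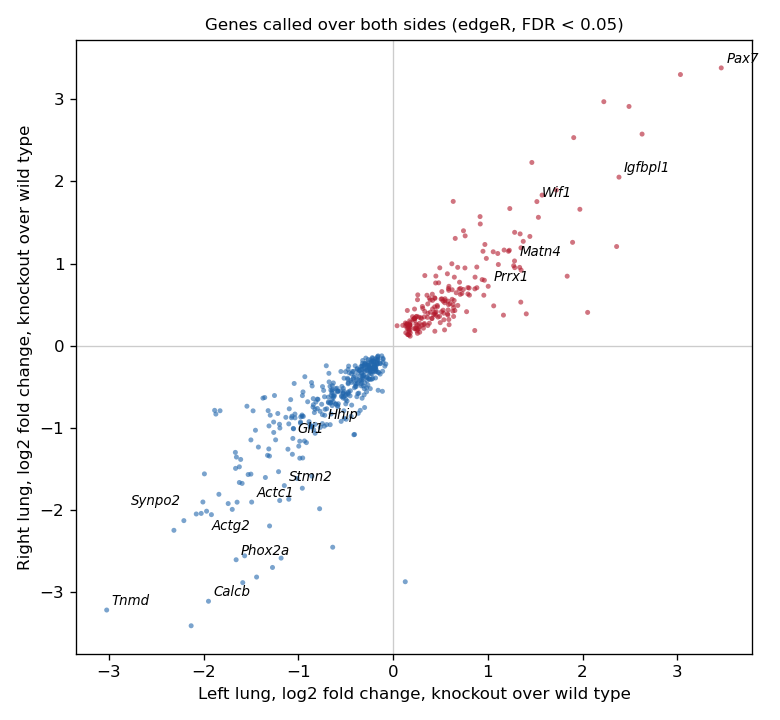
Log2 fold change of knockout-labelled over wild-type libraries in left lungs (x axis) and in right lungs (y axis) for the 543 genes called over both sides, higher in red and lower in blue, with 14 named genes. Values on the 2 sides lie along the diagonal, and Gli1, Actg2, Synpo2 and Phox2a lie in the lower left quadrant. The genes were selected on the mean of the 2 sides, so this selection by itself favours the diagonal. Over all tested genes the Pearson r was 0.669.

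The second comparison asked how left and right lungs differ. Several genes of the Hoxa cluster on chromosome 6 were lower on the left. In wild-type lungs Hoxa6 was the 1 gene called without pairs in the main edgeR fit (-1.25, SE 0.14, adjusted p = 0.00323), at 10.1 ± 1.76 CPM on the left and 24.1 ± 1.18 on the right. Some other fits without pairs called more genes, with counts given below. With pairs, Hoxa7 stood at -1.47 (SE 0.14), Hoxa6 at -1.26 and Hoxa5 at -0.33 (SE 0.05), together with the neighbouring Hoxaas2 (-0.52) and Skap2 (-0.49, SE 0.06), and each was lower on the left in 3 of 3 pairs. In knockout-labelled lungs Hoxa6 (-0.75), Hoxa7 (-0.81) and Skap2 (-0.28) were called in the same direction. Some of these genes overlap on opposite strands and the sources used here do not say whether counting used strand, so Hoxaas2 cannot be told apart from its Hoxa neighbours. The list of Hox genes, with 8 measured members, was called lower on the left in wild-type lungs without pairs (adjusted p = 1.62e-09; adjusted p = 0.0262 with an estimated correlation), and 5 members were lower adjusted over the list alone. D030025E07Rik, a long noncoding RNA gene on chromosome 3, was also lower on the left, at 0.127 ± 0.11 CPM against 3.21 ± 1.07 on the right in wild-type lungs (adjusted p = 0.0785 without pairs and 2.29e-06 with pairs) and at 0.0326 ± 0.0565 against 2.26 ± 1.49 in knockout-labelled lungs (adjusted p = 0.206 and 5.55e-05; SD, n = 3, edgeR).

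In all, these genes included, the paired fit called 63 genes in wild-type lungs, 26 higher and 37 lower on the left, where the fit without pairs called 1 (249 genes at an unadjusted p under 0.05). With the pairs as a random effect in limma-voom, 13 genes were called, 4 higher and 9 lower on the left. The vascular endothelial growth factor gene Vegfd (0.66, SE 0.09), Asb4 (0.42), Scn7a (0.53) and the proteoglycan Podn (0.79) were higher on the left. The haemoglobin genes Hbb-y (0.47, SE 0.05), Hbb-bh1 (0.62), Hbb-bs (0.42) and Hbb-bt (0.42) and the haem synthesis gene Alas2 (0.47) were also higher on the left; reads of Hbb-bs and Hbb-bt may be split between these near-identical copies. Nephronectin (Npnt, -0.51, SE 0.05), Cav1 (-0.49), the retinoic acid genes Cyp26b1 (-0.59, SE 0.09) and Dhrs3 (-0.41), Grem1 (-1.19, SE 0.18), Prrx1 (-0.43) and the neuronal gene Stmn2 (-0.66) were lower on the left. As sets, without pairs, the retinoic acid, neuronal, smooth muscle and Hox lists were called lower and the erythroid and left-right asymmetry lists higher; apart from the Hox list these calls were lost with an estimated correlation (adjusted p = 0.148, 0.201, 0.213, 0.124 and 0.124 with an estimated correlation). With pairs, 9 lists were called: these 6, and BMP and TGF-beta (adjusted p = 0.0465), cardiac (0.0187) and glycolysis genes (0.0218) as lower on the left. No list was called by camera with pairs and an estimated correlation.

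In knockout-labelled lungs no gene was called between left and right without pairs in edgeR (358 genes at an unadjusted p under 0.05, 3 genes called by DESeq2 and 0 by limma-voom), and 43 were called with pairs, 25 higher and 18 lower on the left. With the pairs as a random effect in limma-voom, 2 genes were called, both lower on the left. Scn7a (0.88, SE 0.13), Asb4 (0.33), Fgf5 (1.01, SE 0.20), Rspo3 (0.96, SE 0.21), Irx3 (0.27, SE 0.05) and Igf2 (0.33) were higher on the left, and Npnt (-0.32), Sox2, a transcription factor of the proximal airway (-0.40, SE 0.08), Eya4 (-0.57), Cav1 (-0.35) and Sema3c (-0.25) were lower, besides the Hoxa genes named above. Alb (3.61) and Afp (1.87), made by the liver, were called higher on the left, with the knockout-labelled left library number 1 holding 40.29 and 45.67 CPM; Alb was higher on the left in 2 of 3 pairs. The hepatic list (adjusted p = 0.022; 0.532 with an estimated correlation) and the Hox list (adjusted p = 0.00126; 0.371 with an estimated correlation) were called, and with pairs also the erythroid list, higher on the left (adjusted p = 0.00061). None of these 3 lists was called with pairs and an estimated correlation (adjusted p = 0.533 each with an estimated correlation).

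The side differences of the 2 genotypes, measured in separate libraries, overlapped. With pairs, 17 genes were called in both, 6 higher and 11 lower on the left, against 0.0683 and 0.07 for independent lists of these sizes. Among them were Asb4, Scn7a, Hbb-bs, Gas6 and Lum (higher) and Hoxa6, Hoxa7, Skap2, D030025E07Rik, Npnt, Cav1, Tnfsf13b, Rgs4, Dcx and Lrat (lower). Of the 89 genes called in either genotype, 79 had the same sign in both, and their log2 fold changes correlated with a Pearson r of 0.654 (0.229 over all tested genes; r is across genes, which are not independent replicates). Averaged over genotypes, a contrast added after the data were examined, 127 genes were called, 63 higher and 64 lower on the left, and Hoxa6 was lower on the left in 6 of 6 pairs.

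**Figure D3:**
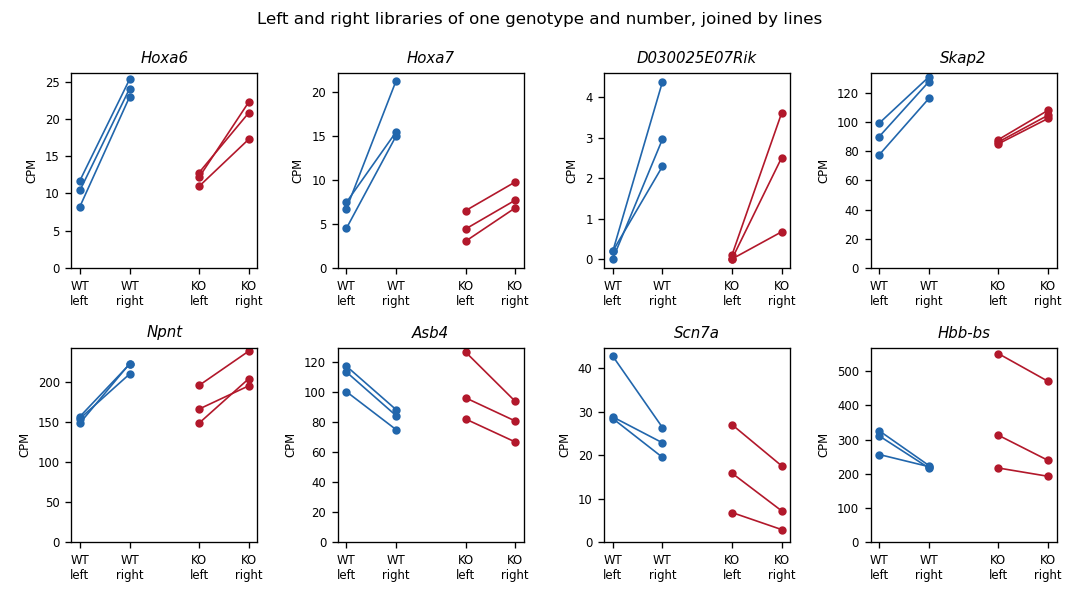
Normalised CPM of 8 genes in left and right libraries, with a line joining the left and right library of one genotype and number, for wild-type (blue) and knockout-labelled (red) lungs. Asb4, Scn7a and Hbb-bs are higher on the left in all 6 pairs, and Hoxa6, Hoxa7, D030025E07Rik, Skap2 and Npnt are lower.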

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

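The left against right contrast averaged over genotypes, on which the last splits in this part were run, was added after the data were examined; the other tests here were planned. In the paired fit the effect of side differed between genotypes for 2 of 9519 genes. Gm10705, an unnamed gene on chromosome 3, was at 45.6 ± 3.94 CPM in wild-type left and 15.98 ± 5.33 in wild-type right lungs, and at 31.5 ± 17.0 and 31.7 ± 12.4 in knockout-labelled left and right lungs (SD, n = 3), an interaction of -1.57 on the log2 scale (SE 0.20, adjusted p = 0.000448, edgeR). Adarb1, an RNA-editing enzyme, was at 124 ± 17.8 and 91.0 ± 6.76 CPM in wild-type left and right lungs and at 156 ± 39.0 and 164 ± 39.5 in knockout-labelled ones, an interaction of -0.51 (SE 0.08, adjusted p = 0.00409). Neither was called by edgeR without pairs, where 0 genes were called and 124 had an unadjusted p under 0.05, and 0 were called by limma-voom with the pairs as a random effect (335 at an unadjusted p under 0.05). These results were singled out because the effect of genotype differed between sides in a test of the difference itself.

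The list of neurons and neural crest genes differed between sides in the effect of the knockout, with a median interaction of 0.33 over 13 genes (camera, adjusted p = 0.0018): its fall was larger on the right. The call was lost with an estimated correlation (adjusted p = 0.7 with an estimated correlation), and no member was called by itself.

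Other splits of the libraries were run for each comparison. With 3 libraries or pairs against 3 there are 10 splits, too few for a share under 0.05. The real split gave 112 genes in left lungs (highest other split 0), 144 in right lungs (0) and 543 over both sides (12). Left against right without pairs, it gave 1 in wild type (highest other 1; 2 of the 10 splits, the real one included, gave as many) and 0 in knockout-labelled lungs (highest other 6; all 10 gave as many). Among splits that part all 3 pairs the highest other was 0 in each. The interaction gave 0 in all 10. For left against right averaged over genotypes with pairs as blocks, 32 splits that swap sides within pairs could be made. The real one gave 127 genes and the highest other 26. Only the real one, 1 of the 32, reached the real count, a share under 0.05 and the smallest that 32 splits can give. The pairs were a hint from the same data and the contrast was added after these were examined, so this share describes the data and does not exclude chance.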

How the results depend on the processing

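DESeq2's size factors, total library size, a minimum of 1 CPM, limma-voom and leaving out the X chromosome kept all 6 counts within 1.5 times. Of 3342 values of single genes under alternatives, 2905 kept direction and side of the threshold, 424 kept direction but were no longer called, 8 were newly called, 4 uncalled values near 0 (Gli1, Hhip and Intu between wild-type sides) changed sign, and 1 reversed: Xist with its own level as covariate (0.0005584), by construction. The Xist covariate, the counts without chromosome 3, the fits without a pair and the list tests with pairs were chosen after seeing the data; the planned covariate from Y-linked genes was not run, since those genes were not analysed here. The cause of the shifts below was not tested unless given.

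Counts are ordered as left, right and mean (knockout against wild type), left against right in wild type and in the knockout, and interaction. As reported they are 112, 144, 543, 1, 0 and 0. Without a filter, which adds low genes and changes the shared estimate of spread, they were 510, 595, 1084, 46, 31 and 6. DESeq2's Wald test gave 195 and 219 for left and right, and 11 and 3 between sides. With the number as a replicate block shared by genotypes the left count was 177 and the wild-type side count 2. With pairs as replicate block the side counts were 63 and 43 and the interaction 2; as a random effect in limma-voom they were 13 and 2, with 344 for the mean. Left and right counts summed gave 141, with fewer samples. Only the groups compared in the fit gave 49 on the left and 8 between wild-type sides. With Xist as covariate the counts were 389, 522 and 866, 295 of them shared with the 543. Without chromosome 3, 92, 107 and 422 genes were called.

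Leaving out 1 library gave 45 to 85 (left), 68 to 124 (right), 354 to 569 (mean), 1 to 2 (wild-type sides), 0 to 1 (knockout sides) and 0 (interaction). Leaving out both libraries of a number gave 263 to 636 for the mean. The left count moved by over 1.5 times without wild-type left 1, the right count without wild-type right 2 or knockout right 3 (68 each), and the mean without wild-type right 2, wild-type pair 2 (263) or knockout pair 3 (331). The side counts moved without wild-type left 2 (2) and without knockout left 1, left 2 or right 2 (1 each). List calls, in the same order, were 4, 6, 5, 6, 2 and 1 as reported, 1, 1, 1, 1, 0 and 0 with an estimated correlation, and 5, 5, 5, 7, 3 and 1 with a replicate block by number. With pairs as replicate block, the list calls between sides were 9 and 3 and those of the interaction 5, and 0 each with an estimated correlation as well. Apart from the counts given here, a block moved none of the counts of genes or lists by over 1.5 times. Of the listed genes, 30.6% had enough counts to be tested, and 13740 to 14066 had any count in a library. An effect of depth was not tested.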

Other observations

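The tests of the whole of chromosome 3 and of its part beyond 10 Mb, of pseudogenes, of the Xist slope, of escape genes and of Hoxd genes, and the genes named in the next paragraph, were chosen only after the result was seen; the tests of genes near Intu and of the spread of Xist were written down before their results were seen.

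Other single genes were lower in knockout-labelled lungs over both sides; they were picked from the called genes and stand for no group. Ppbp, a platelet chemokine, stood at -1.55 (SE 0.25, adjusted p = 0.00177, edgeR), Gp9 at -1.14 (SE 0.28), Tubb1, the platelet tubulin, at -1.08 (SE 0.17) and Pf4 at -0.76 (SE 0.12). The growth factor gene Igf1 stood at -0.75 (SE 0.08, adjusted p = 7.03e-05) and the chemokine gene Cxcl12 at -0.62 (SE 0.04, adjusted p = 2.23e-07). Of the 10 genes of the erythroid list none was called by edgeR over both sides, also adjusted over the list alone, and the list was not called (adjusted p = 0.995).

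Chromosome 3, which carries Intu, held more called genes than the rest. Of 872 tested genes on it, Intu left out, 91 (10.4%) were called over both sides, against 452 of 8646 elsewhere (5.23%; odds ratio 2.11, 95% interval 1.65 to 2.68, Fisher's exact test, two-sided p = 8.99e-09), and Fhdc1 (-1.33), Rbm46 (0.85), Capza1 (-0.82) and Vps45 (-0.62) are on it. A candidate explanation is sequence of another strain, linked to the targeted allele and differing from the reference or in expression. Within 10 Mb of Intu, 11 of 76 genes were called (odds ratio 2.83, 1.34 to 5.45, Fisher's exact test p = 0.00368), which goes with that, but the excess also held further away on the chromosome (odds ratio 2.03), which a short linked segment would not give. In stretches of 20 Mb along chromosome 3, 15.5% of genes were called from 20 to 40 Mb. The share was 6.41% from 40 to 60 Mb and 7.53% to 12.2% in the others. Intu starts at position 40531286, close to the border at 40 Mb, so its neighbourhood is divided between the stretches with the highest and the lowest share. Bbs7, Spry1 and Fat4 lie in the stretch from 20 to 40 Mb. The stretches therefore do not show whether the excess is centred on Intu. Reads shared with pseudogene copies were tested over all chromosomes: 34 of 735 annotated pseudogenes were called (odds ratio 0.788, 0.535 to 1.13, Fisher's exact test p = 0.214), which decides nothing for single families. An effect of the genotype stays open and was not tested: Gli1, Actg2 and Myl9 lie on other chromosomes, whereas Synpo2, Stmn2, Wnt2b, Bbs7, Fat4 and Spry1 lie on chromosome 3. Of these, Bbs7, Fat4 and Spry1 lie within 10 Mb of Intu.

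The sexes may differ between the genotypes. Xist spanned 1271 to 2269 CPM in wild-type libraries and 107.2 to 985.4 in knockout-labelled ones, up to 9.19-fold within a group, which is between the bounds set for single sexes and mixed groups and does not decide whether groups hold both. All 6 measured genes known to escape X inactivation had negative values (median -0.282; other X genes 0.0176) and 5 were called, led by Eif2s3x (-0.42) and Pbdc1 (-0.33), with Utp14a (-0.07) not called, which is consistent with a lower share of female cells there. As the whole cause of the 505 autosomal calls, the tables argue against it: the change that Xist's slope within groups predicts was -0.105 of the observed change at the median (quartiles -0.37 and 0.193), and all 505 kept their direction with Xist as covariate. That slope rests mainly on the knockout-labelled libraries, since Xist spanned at most 1.71-fold within a wild-type group. Other differences between the knockout-labelled pairs enter it too, so the argument assumes that these do not follow Xist. For single genes a difference of sexes cannot be excluded, since 279 of the 505 were called with the covariate, with standard errors 1.51 times as large at the median.

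Several Hoxa genes, among them Hoxa6 and Hoxa7, were lower on the left in both genotypes. The median was -0.254 over 7 tested Hoxa genes averaged over genotypes with pairs as blocks. In that edgeR fit Hoxa3 (-0.17, adjusted p = 0.099) and Hoxa4 (-0.15, adjusted p = 0.177) were not called. A candidate explanation is more tissue from further back along the body axis in the right samples, which would also move Hoxd genes. Only Hoxd8 and Hoxd13 were tested, at means under 4 CPM, and their median of -0.192 (SE 0.26 and 0.20) cannot be told apart from either outcome, because they are too few and too low. Hoxa2, within the same cluster, stood at 0.06 (SE 0.05) while Hoxa5, Hoxa6 and Hoxa7 were lower. A side difference in the regulation of the cluster stays open and was not tested.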
